A study of Rattus norvegicus with 12 samples.

How the data were processed

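The series holds 12 RNA sequencing libraries of rat CD4+ T cells that recognise myelin basic protein, an antigen of the myelin sheath. The cells carry green fluorescent protein and were sorted by flow cytometry in the cold from Lewis rats with experimental autoimmune encephalomyelitis, an autoimmune inflammation of the central nervous system (CNS) that such cells drive. Per the labels, 3 libraries each came from blood, cerebrospinal fluid (CSF), the meninges of the spinal cord and CNS parenchyma, and libraries of messenger RNA were made with an Illumina TruSeq protocol. Groups and library numbers were taken from the sample titles and tissue labels. The labels do not say whether the numbered libraries of a compartment came from separate animals, so p-values measure only the spread between these libraries, which may be partly technical.

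The deposited files hold whole-number read counts per gene, not normalized, one file per library with the same 26405 Ensembl rat gene identifiers. The submitters' processing notes name CASAVA 1.8.2, STAR, SAMtools, HTSeq and DESeq2, without stating the role of each. The genome build, the annotation release and whether counting used strand are not given in the sources used here. Each file closes with 5 summary lines, which were kept out of library sizes and tests. Of all entries in a file, genes and summary lines together, 35.8% to 65.2% were listed as aligned to several places. Another 15.5% to 21.9% were listed as outside any gene and 0.0412% to 0.0911% as ambiguous between genes. Whether a read aligned to several places was entered more than once is not given. What is called a share of reads below is therefore a share of entries. The remaining 2 summary lines were 0 in all files. Because only reads aligned to 1 place were counted, genes with near-identical copies are under-counted, and where strand was not used, reads of overlapping antisense genes would be mixed.

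The files do not pair identifiers with gene names. The reference table supplied with the data has an Ensembl identifier in 0 of its 47357 rows, so 0 identifiers matched a name. The 35 lists of T cell and other cell type genes that were planned, and the planned rule for naming genes, both need names and could not be used. In their place, 4 identifiers are printed. They are the 2 with the largest rise and the 2 with the largest fall from blood to CNS parenchyma among genes past the threshold, with a mean of at least 10 CPM, the count of a gene scaled to a fixed total per library, in the higher group and 3 libraries that all lay above the other 3. The planned rule named 5 genes each way in each comparison and required a name. Leaving out the name and limiting it to 4 genes of 1 comparison were decided after the files had been read.

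Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 11498 genes. In the library where they held the smallest share of gene counts, that share was 99.9%. Libraries were scaled by the trimmed mean of M values (TMM). All 12 libraries entered 1 quasi-likelihood fit with the compartment as the only term, so that the 4 groups shared 1 estimate of the spread. Each of 6 pairwise comparisons was a two-sided contrast of group means, and an F test asked for any difference among the 4 compartments. A gene was called when its Benjamini-Hochberg adjusted p over all genes tested was under 0.05, and adjusted p-values in the text come from this edgeR test unless another tool is named. The common biological coefficient of variation was 10.7%. Standard errors of log2 fold changes were derived from the F statistic. Distances between libraries are root mean squared differences of log2 CPM over the genes tested, with a prior count of 2. The position of a library between blood and parenchyma is its projection on the line from the blood mean (0) to the parenchyma mean (1) over the genes called between those groups. CSF and meninges positions were compared with a two-sided exact permutation test, which with 3 against 3 libraries cannot give a p below 0.1.

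Total gene counts ran from 11277725 to 22056664 per library, so that 3 counts, the limit that a count of 0 allows, correspond to between 0.136 and 0.266 CPM in a single library. Folds against a group without counts are given against 3 counts over the 3 libraries of that group together. Ratios of summed counts carry exact 95% binomial intervals. Such intervals and floors cover counting error only, since reads carry no molecular identifiers.

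The count functions were tested on simulated data before use. Negative binomial counts were drawn from the real means, library sizes and dispersions, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in the parenchyma libraries. In the simulated comparison of CNS parenchyma with blood, on 11427 genes passing the filter, 53.7%, 88.1% and 92.4% of these, in that order, were called in the right direction, and 5.45% of calls were false. Groups simulated at positions 0.3 and 0.6 were placed at 0.307 and 0.591.

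Library pairs within a compartment were compared for duplicates over genes with more than 20 counts in a pair. The chi-square per degree of freedom was 3.61 to 31.0 over the 12 pairs, above the 1 that sampling noise gives, so all libraries were counted apart. The titles give the same numbers 1 to 3 in each compartment. The deviations of libraries from their group means correlated across genes with a median of 0.278 for the 18 pairs of the same number and -0.175 for pairs of different numbers. Since deviations within a compartment cancel out for each gene, positive values for same numbers bring negative ones for different numbers. The value of -0.175 is therefore no chance level, and the 18 pairs are not independent of one another. The correlation was above 0.1 for 17 of the 18 pairs, the exception being number 3 in meninges and blood (0.0766). Among choices of the best correlated library in another compartment, 35 of 36 fell on the same number. As a correlation above 0.1 was asked of each pair, the numbers were read as pairing the libraries in 5 of the 6 comparisons, on the evidence of the data alone. Meninges against blood missed this rule by 1 pair, although a pairing in the other comparisons would imply it there too. The fit stayed unpaired, as fixed before the data were examined, and the fit with the number as a block is given beside a result where it moves a count by more than 1.5 times or changes a call.

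Alternatives fixed before the data were examined were relative log expression scaling, library size alone, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom (limma 3.58.1), the replicate block, an adjusted p under 0.01, a minimum fold of 1.5 (glmTreat), fits of only the 6 libraries compared, and each library left out in turn. For distances they were 1 minus the Spearman correlation, a prior count of 0.5 and the 500 most variable genes, and for positions all genes tested and a prior count of 0.5. Chosen after seeing the data were thinning every library to 11277725 counts, alone and with the replicate block, leaving out the 2 libraries with most reads aligned to several places, leaving out the 4 libraries numbered 2, subtracting the spread between replicates from positions, comparing the positions of CSF and meninges within library numbers, the shares of higher genes above 10 CPM under the block, and regroupings of libraries within numbers. Because comparisons that share libraries share chance values, overlaps of calls are given beside the mean of 20 simulated sets of unchanged libraries and the overlap that independent lists of the same sizes would have.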

Results

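Expression profiles were measured in CD4+ T cells specific for myelin basic protein, recovered from blood, CSF, spinal cord meninges and CNS parenchyma of rats with experimental autoimmune encephalomyelitis, with 3 libraries per compartment. In this model such T cells pass from the blood into the CNS and its coverings. The comparisons ask how the cells differ between these places and which places hold cells with similar profiles. Total gene counts were 13267031 to 17438057 in blood, 14279851 to 22056664 in CSF, 11277725 to 15596984 in meninges and 15361310 to 17965790 in parenchyma. Between 14525 and 16096 genes had at least 1 count in 11 of the libraries, and 18299 in meninges replicate 3. The share of reads aligned to several places was 65.2% in blood replicate 3 and 61.4% in meninges replicate 2, against 35.8% to 43.9% in the other 10 libraries. The 10 most abundant genes of each library took 7.57% ± 0.0839 (SD, n = 3) of gene counts in blood, 8.29% ± 0.630 in CSF, 8.54% ± 0.197 in meninges and 9.75% ± 0.282 in parenchyma.

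T cells of the 4 compartments had distinct profiles. Expression differed among the compartments for 6183 of 11498 genes tested (53.8%, F test). The first principal component, with 54.5% of the variance, placed blood at -53.0 ± 4.87 (SD, n = 3), CSF at -0.351 ± 1.94, meninges at 12.8 ± 3.06 and parenchyma at 40.5 ± 3.77. On the second component, with 18.5% of the variance, CSF cells lay at -28.3 ± 10.5, below meninges at -3.80 ± 7.97, blood at 13.2 ± 11.9 and parenchyma at 18.9 ± 5.92. In each compartment the library numbered 2 had the lowest value on this component.

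**Figure D1:**
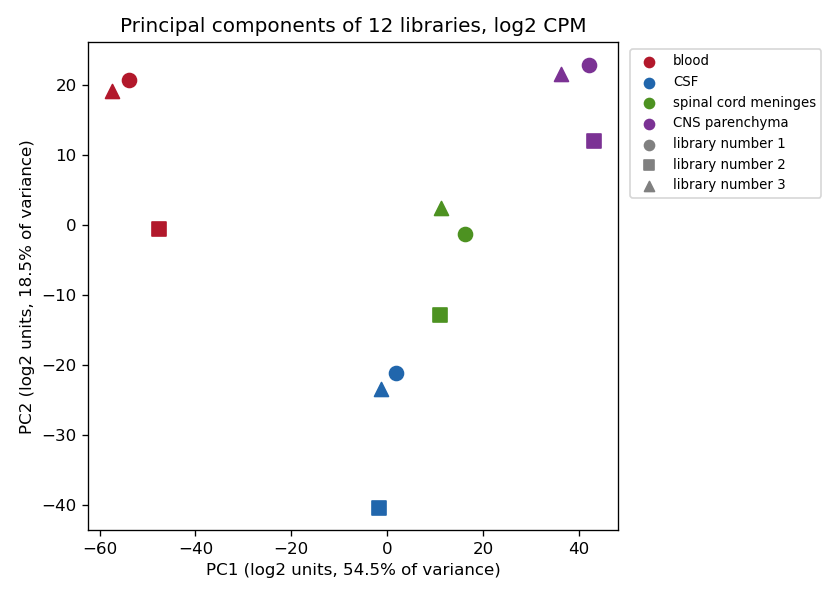
First and second principal components of log2 CPM over the 11498 genes tested. Each point is a library, coloured by compartment and shaped by the library number in the titles. Blood lies at -53.0 on average on the first component and parenchyma at 40.5, with CSF and meninges between them.

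**Figure D2:**
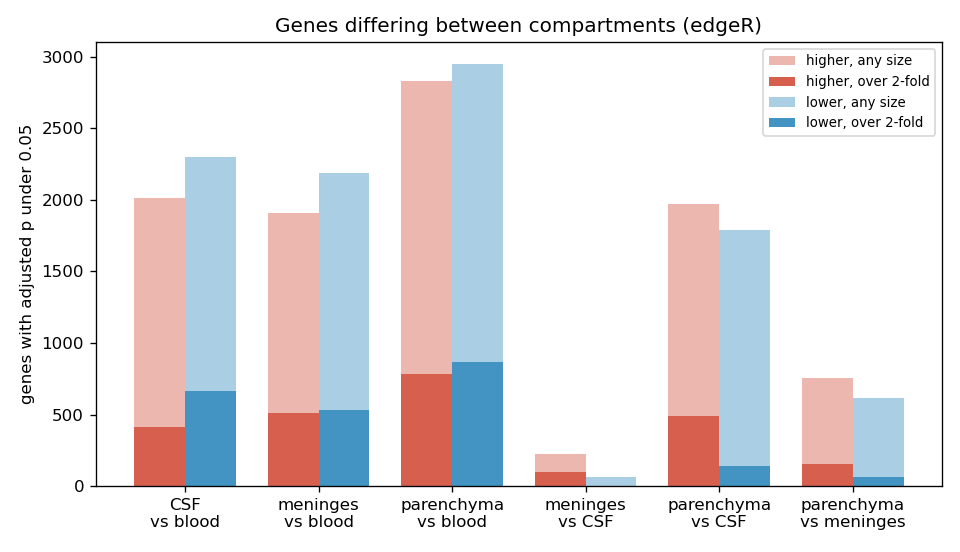
Genes with an edgeR adjusted p under 0.05 in each of the 6 comparisons. The first compartment is higher (red) or lower (blue) than the second. Pale bars count all such genes, dark bars those that differed more than 2-fold. Meninges against CSF has the smallest count, 289 genes, and parenchyma against blood the largest, 5783.

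T cells in the CSF differed widely from those in the blood. Of the genes tested, 2010 were higher and 2300 lower in CSF, and 412 and 663 of these differed more than 2-fold. The genes more than 2-fold higher in CSF took 5.68% ± 0.330 (SD, n = 3) of gene counts in CSF and 2.11% ± 0.587 in blood. They also took 5.37% ± 0.30 in meninges and 6.55% ± 0.532 in parenchyma. Those more than 2-fold lower in CSF fell from 3.71% ± 0.388 of gene counts in blood to 1.40% ± 0.0778. The median fold among called genes was 1.46. Requiring a change beyond 1.5-fold left 930 genes.

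T cells in the spinal cord meninges differed from blood T cells in a similar number of genes. In meninges 1908 genes were higher and 2187 lower than in blood, 511 and 533 of them more than 2-fold. The genes more than 2-fold higher took 1.84% ± 0.378 (SD, n = 3) of gene counts in blood and 5.21% ± 0.114 in meninges. Those more than 2-fold lower took 4.14% ± 0.163 in blood and 1.75% ± 0.0915 in meninges. At least 10 CPM in meninges with under 0.5 CPM in blood was seen for 6 of the genes called higher, and the reverse for 1 gene. Requiring a change beyond 1.5-fold left 913 genes.

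The widest difference was between T cells in the CNS parenchyma and T cells in the blood. In parenchyma 2831 genes were higher and 2952 lower, 50.3% of the genes tested, and 782 and 865 of them differed more than 2-fold. The genes more than 2-fold higher took 3.05% ± 0.570 (SD, n = 3) of gene counts in blood, 6.58% ± 0.221 in CSF, 7.21% ± 0.193 in meninges and 9.73% ± 0.679 in parenchyma. Those more than 2-fold lower took 7.51% ± 0.147 in blood, 3.81% ± 0.132 in CSF, 3.74% ± 0.173 in meninges and 2.63% ± 0.149 in parenchyma. At least 10 CPM in parenchyma with under 0.5 CPM in blood was seen for 13 of the genes called higher, and the reverse for 4 genes. Requiring a change beyond 1.5-fold left 1747 genes. Over all alternatives tried the genes higher were 39.4% to 51.1% of those called against blood in CSF, 46.4% to 51.8% in meninges and 42.3% to 51.7% in parenchyma, so that which direction held more genes depends on the setting.

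The files do not pair gene identifiers with names, so 4 genes with the largest changes from blood to parenchyma are given by identifier, and their position and function are not given. ENSRNOG00000011406 was higher at each step. Its level was 0.138 ± 0.126 CPM (SD, n = 3) in blood, 2.10 ± 1.34 in CSF, 25.9 ± 6.42 in meninges and 93.5 ± 27.2 in parenchyma. The log2 fold change was 9.27 (SE 0.52, adjusted p = 1.76e-08) from blood to parenchyma, on 7 counts in the 3 blood libraries, 5 of them in replicate 1, and 4533 in parenchyma. It was 3.74 (SE 0.87, adjusted p = 0.00453) from blood to CSF, 3.69 (SE 0.37, adjusted p = 0.000117) from CSF to meninges and 1.85 (SE 0.27, adjusted p = 0.00103) from meninges to parenchyma. Without blood replicate 1 it was 10.34 from blood to parenchyma and 4.81 from blood to CSF. ENSRNOG00000022298 had 0 counts in all 3 blood libraries, and 0.290 ± 0.294 CPM in CSF, 1.11 ± 0.539 in meninges and 14.7 ± 6.96 in parenchyma. Set against 3 counts over the blood libraries as the floor, it was 244-fold higher in parenchyma than in blood (adjusted p = 5.26e-06). From the counts themselves, 715 in parenchyma against 0 in blood, the counting interval of the ratio began at 198. ENSRNOG00000022298 was higher in parenchyma than in meninges by 3.68 on the log2 scale (SE 0.50, adjusted p = 0.00107). Its difference between CSF and blood, on 18 CSF counts of which 14 were in replicate 1, had an adjusted p of 0.0705, and of 0.00330 with the replicate block. That between meninges and CSF had an adjusted p of 0.275, and of 0.0217 with the block. Over all alternatives tried the first ran from 2.09e-05 to 0.255 and the second from 0.000281 to 1. Both low ends came from the fit without the filter, whose p-values are not comparable with the others.

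The 2 genes with the largest falls from blood to parenchyma were ENSRNOG00000049424 and ENSRNOG00000029886. ENSRNOG00000049424 was at 11.5 ± 6.25 CPM (SD, n = 3) in blood and had 3 counts in the parenchyma libraries together, a ratio of 187 with a counting interval of 63.7 to 910 (adjusted p = 6.29e-06). ENSRNOG00000029886 was at 13.4 ± 8.29 CPM in blood and had 4 counts in parenchyma, a ratio of 165 with a counting interval of 64.1 to 607 (adjusted p = 5.82e-05). The log2 fold change of the former was -7.35, and -8.12 without parenchyma replicate 3, and that of the latter -7.20, and -6.56 without blood replicate 1. In CSF both were also lower than in blood, at 0.232 ± 0.110 CPM (adjusted p = 2.12e-05) and 0.304 ± 0.389 CPM (adjusted p = 0.000182). For the latter the log2 fold change of CSF against blood was -5.37, and -7.22 without CSF replicate 2 and -4.73 without blood replicate 1. In meninges they stood at 3.15 ± 2.52 and 3.78 ± 3.94 CPM, with 6.05 and 8.32 CPM in replicate 3 and 1.44 to 1.93 CPM in the other libraries. Blood replicate 1 held 18.7 and 22.8 CPM, against 7.50 to 9.72 CPM in the other blood libraries. The 2 genes thus varied together within blood and within meninges, for a reason that was not tested.

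**Figure D3:**
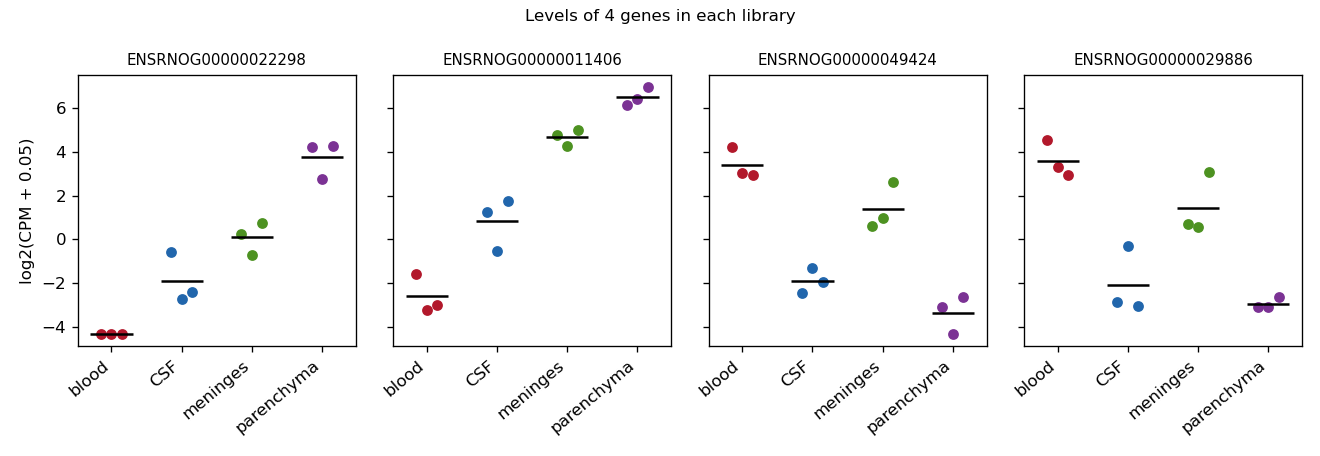
Levels of the 4 genes in each library, as log2(CPM + 0.05). Points are libraries, lines are means of the 3 values of a compartment. The 2 genes on the left rise from blood to parenchyma (0.138 to 93.5 CPM for ENSRNOG00000011406), and the 2 on the right fall, with meninges replicate 3 above the other meninges libraries.

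Cells in all 3 CNS sites shared much of their difference from blood cells. In CSF, meninges and parenchyma alike, 1250 genes were higher than in blood and 1556 lower, counts chosen after seeing the data. Independent lists of the same sizes would share 82.1 and 112 genes. Sets of simulated unchanged libraries, with blood redrawn and used in all 3 comparisons, give almost no calls and shared 0 on average. At an adjusted p under 0.01 the count of genes higher in all 3 was 762. Across genes, the log2 fold changes against blood correlated at 0.858 for CSF and meninges, 0.741 for CSF and parenchyma and 0.895 for meninges and parenchyma, against 0.498, 0.506 and 0.490 in the simulated unchanged sets. The covariances were 0.36, 0.41 and 0.52, against 0.022 in each simulated pair. Genes are not independent replicates. The simulated covariances already hold what sharing blood libraries adds at the estimated spread between libraries, and the excess lies beyond that. As 3 blood libraries cannot be divided into parts of at least 2, a deviation common to them may still add to the excess.

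Meninges and CSF held the most similar cells of the 6 pairs. In meninges 227 genes were higher and 62 lower than in CSF, 2.51% of the genes tested, with 97 and 4 of them more than 2-fold. The 97 genes took 0.113% ± 0.0159 (SD, n = 3) of gene counts in blood, 0.150% ± 0.0243 in CSF, 0.475% ± 0.0472 in meninges and 0.891% ± 0.118 in parenchyma. Of the 227 genes 216 were also higher in parenchyma than in CSF, and of the 62 genes 61 were also lower. Independent lists would share 38.9 and 9.65, and simulated unchanged libraries, which give almost no calls, 0 on average. Part of the excess may come from the CSF libraries that both comparisons use. With the library numbers as a replicate block 1046 genes were called, 604 higher and 442 lower, with 166 and 8 more than 2-fold, all 289 of the unpaired fit among them, so that the share higher was 78.5% without and 57.7% with the block. The count was 176, 139 and 175 without CSF replicate 1, 2 or 3, and 126 and 130 without meninges replicate 1 or 3. It was 505 with DESeq2, 890 without the filter, 107 at an adjusted p under 0.01 and 53 beyond 1.5-fold. The share higher was 65.3% with DESeq2 and 60.6% without the filter, but 89.7% at an adjusted p under 0.01 and 98.1% beyond 1.5-fold.

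Parenchymal T cells differed from CSF T cells in many more genes than meningeal cells did. In parenchyma 1970 genes were higher and 1789 lower than in CSF, and 489 and 141 of them differed more than 2-fold. The genes higher were 52.4% of those called, 46.4% when libraries were scaled by their size alone and 82.8% of those beyond 1.5-fold. The 489 genes took 1.11% ± 0.0910 (SD, n = 3) of gene counts in CSF, 2.00% ± 0.110 in meninges and 3.31% ± 0.180 in parenchyma, and 0.969% ± 0.104 in blood. The 141 genes took 0.355% ± 0.0479 in CSF, 0.275% ± 0.0217 in meninges and 0.154% ± 0.010 in parenchyma. The mean meningeal level lay between the CSF and parenchyma means for 94.9% of the genes higher and 92.2% of the genes lower in parenchyma. Meningeal libraries simulated from the CSF means alone would lie between for 49.0% and 50.5%, and from the parenchyma means alone for 51.1% and 49.2%. Such values follow from drawing around a mean that bounds the interval. As the genes were called on these same CSF and parenchyma libraries, meninges cells equal to either would lie between more often than that. By how much was not measured. The count was 2276 at an adjusted p under 0.01 and 478 beyond 1.5-fold.

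Between CNS parenchyma and meninges the difference was of intermediate extent. In parenchyma 757 genes were higher and 618 lower than in meninges, 11.96% of the genes tested, with 155 and 61 of them more than 2-fold. The 155 genes took 0.263% ± 0.0229 (SD, n = 3) of gene counts in meninges and 0.700% ± 0.114 in parenchyma, against 0.0720% ± 0.00240 in blood and 0.101% ± 0.00713 in CSF. The 61 genes took 0.0916% ± 0.00910 in meninges and 0.0371% ± 0.00336 in parenchyma, against 0.265% ± 0.00975 in blood. The genes higher were 55.1% of those called, 38.5% when libraries were scaled by their size alone and 84.2% of those beyond 1.5-fold. With the replicate block 2428 genes were called, 1305 higher and 1123 lower, among them all 1375. The count was 888 and 821 without parenchyma replicate 1 or 2, 899, 883 and 739 without meninges replicate 1, 2 or 3, 764 without blood replicate 3 and meninges replicate 2, 539 at an adjusted p under 0.01 and 95 beyond 1.5-fold.

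Distances between libraries gave nearly the same order as the counts of genes, with CSF and meninges changing places in their distance to blood. The mean root mean squared difference was 0.45 ± 0.05 log2 units (SD over 9 library pairs) between meninges and CSF, 0.50 ± 0.05 between parenchyma and meninges, 0.65 ± 0.06 between parenchyma and CSF, 0.70 ± 0.07 between CSF and blood, 0.73 ± 0.04 between meninges and blood, and 0.93 ± 0.04 between parenchyma and blood. Within compartments the means were 0.35 to 0.40. Outside its own compartment the nearest library of each CSF library was a meninges library, and of each meninges library a CSF library. Each parenchyma library had a meninges library nearest. Pairs of libraries are not independent, so no test was made on distances.

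Between the blood mean at 0 and the parenchyma mean at 1, CSF libraries lay at 0.532 ± 0.0253 (SD, n = 3) and meninges libraries at 0.686 ± 0.0333, over 5783 genes. Such a position leaves out differences that do not run along the line. The CSF mean lay between the blood and parenchyma means for 64.2% of these genes higher and 72.2% of those lower in parenchyma. For the meninges mean the shares were 80.5% and 83.7%. The lowest meninges library, at 0.661, lay above the highest CSF library, at 0.560. The difference of 0.154 had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. Within the numbers 1, 2 and 3, read as pairing these libraries, the differences were 0.164, 0.150 and 0.147 (SD 0.00889, n = 3). A two-sided exact sign-flip permutation test, chosen after seeing the data, gave a p of 0.25, the smallest that 3 pairs can give. Along a line from the CSF mean at 0 to the parenchyma mean at 1, a measure chosen after seeing the data, meninges libraries lay at 0.436 ± 0.0659 (SD, n = 3). On that line blood libraries lay at -0.0423 ± 0.0623 (SD, n = 3), so blood and CSF differed little along it.

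**Figure D4:**
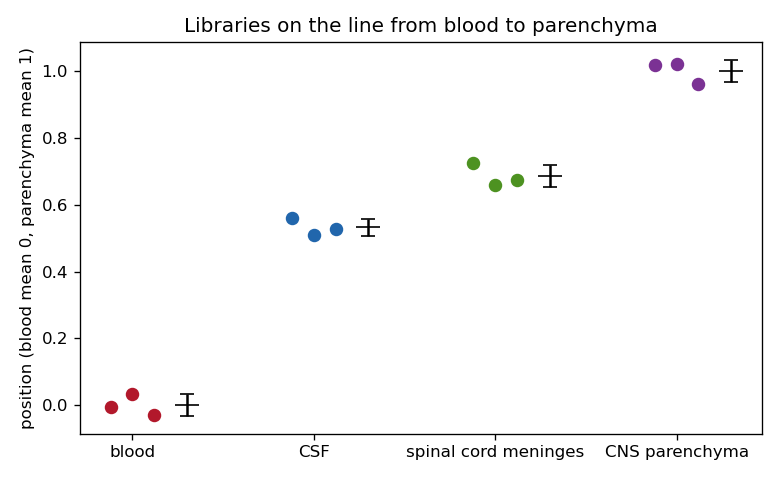
Position of each library on the line from the blood mean (0) to the parenchyma mean (1) over the 5783 genes called between these compartments. Points are libraries, and bars give the mean and SD of 3 libraries. The CSF libraries lie between 0.510 and 0.560 and the meninges libraries between 0.661 and 0.724.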

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

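Thinning, with and without the block, leaving out groups of libraries and subtracting the replicate spread were chosen after the data were seen. The count of genes differing among the 4 compartments stayed within 1.5 times of 6183 under all alternatives tried, from 4366 to 7569, the latter with the replicate block. For CSF against blood it ranged from 3274 to 4057 with a library left out and was 2725 at an adjusted p under 0.01 and 930 beyond 1.5-fold. For meninges against blood it was 3182 to 3723 with a library left out, 2649 at an adjusted p under 0.01, 913 beyond 1.5-fold, and 5148 with the replicate block, where 1 of the 3 pairs of the same number correlated under the 0.1 asked of each pair. For parenchyma against blood it was 5066 to 5461 with a library left out and 1747 beyond 1.5-fold. For parenchyma against CSF it was 3050 to 3488 with a library left out, 2276 at an adjusted p under 0.01 and 478 beyond 1.5-fold. For meninges against CSF it was 126 to 288 with a library left out, 107 at an adjusted p under 0.01, 53 beyond 1.5-fold, 505 with DESeq2, 890 without the filter, 1046 with the replicate block, 882 with the block after thinning and 539 without the 4 libraries numbered 2. For parenchyma against meninges it was 739 to 1402 with a library left out, 539 at an adjusted p under 0.01, 95 beyond 1.5-fold, 2428 with the block, 2287 with the block after thinning and 764 without the 2 libraries with most reads aligned to several places. The lower counts at stricter thresholds follow from their construction. With fewer libraries the count depended on which library was left out. For meninges against CSF it was 288 without meninges replicate 2 and 126 without meninges replicate 1. For parenchyma against meninges it was 1402 without parenchyma replicate 3 and 739 without meninges replicate 3. The cause of this and of the other changes was not tested. Besides these counts, the values given with the results and the patterns over several comparisons, the replicate block changed no other call. Thinning alone left all 7 counts within 1.5 times, and scaling moved the median log2 fold change of all genes by less than 0.1. Without the filter, ENSRNOG00000011406 in parenchyma against blood had an adjusted p of 6.42e-183 at a log2 fold change of 9.30. In the main fit these were 1.76e-08 and 9.27. P-values and counts without the filter are therefore not comparable with the others, for a reason that was not tested. Distances with a prior count of 0.5 were 0.79 for meninges and blood, 1.006 for parenchyma and blood, 0.52 for meninges and CSF, 0.73 for parenchyma and CSF and 0.56 for parenchyma and meninges. As 1 minus the Spearman correlation they were 0.0272 for CSF and blood and, in the order just given, 0.0305, 0.0486, 0.00918, 0.0220 and 0.0114. Over the 500 most variable genes they were 2.11 and then 2.38, 3.15, 1.39, 2.17 and 1.54. These are other scales, and meninges and CSF were nearest and parenchyma and blood farthest on each. The CSF position was 0.514 to 0.586 with a library left out, the latter without blood replicate 2, and 0.525 to 0.534 under the other alternatives. The meninges position stayed within 1 SD throughout, from 0.663 to 0.696. Of 451 values of the 4 identifiers under alternatives, 416 kept direction and side of the threshold, 25 lost and 8 gained the call, and 2 changed sign. Both were ENSRNOG00000029886 in parenchyma against CSF, not called, whose log2 fold change was -1.83 and became 0.14 without the libraries numbered 2 and ranged from -2.35 to 0.027 with a library left out, the latter without CSF replicate 2. Of the counts of genes with a pattern over several comparisons, 165 values under alternatives stayed within 1.5 times, 8 were higher and 19 lower. The planned tests of gene lists and their alternatives were not run, for want of gene names. Depth limits genes under about 0.2 CPM, where a library holds about 3 counts.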

Other observations

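Tests chosen only after the results were seen are the 2 comparisons of library numbers with the share of reads aligned to several places, the shares of higher genes above 10 CPM under the replicate block, the regroupings within library numbers, the test of a single ratio of excess over CSF, the counts of genes with a pattern over several comparisons, and the combination of thinning with the replicate block. In CNS parenchyma 665 genes were higher, and 477 lower, than in each of the other 3 compartments, where independent lists would share 31.9 and 24.7 and simulated unchanged libraries, which give almost no calls, 0 on average. Part of the excess may come from the parenchyma libraries that the 3 comparisons share. The genes higher in parenchyma had median log2 differences of 0.92 to blood, 0.76 to CSF and 0.51 to meninges, and those lower had -0.85, -0.60 and -0.44. With the replicate block the counts were 1059 and 842, and when libraries were scaled by their size alone 504 and 708, so that which direction held more genes depends on scaling. Without meninges replicate 3 or parenchyma replicate 2 they were 385 or 420 higher, and without meninges replicate 3, 2 or 1 or parenchyma replicate 1 or 2 they were 264, 284, 316, 293 or 296 lower. Counted apart from this pattern, which can hold the same genes, 427 genes were higher in CSF than in blood and higher again in parenchyma than in CSF, and 427 took the same 2 steps downward, where independent lists would share 344 and 358. The latter count was 659 with the block, and the counts were 363 and 497 with scaling by size alone.

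The counts behind each comparison were set against other groupings of the same libraries. Among 100 random regroupings of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many genes as the 6183 that differed among compartments. The highest of the others gave 5344. A share of 1 in 100 makes a random grouping of these libraries an unlikely source of that count. It does not cover chance differences between animals or preparations, which the labels do not tell apart. As the numbers were read as pairing most libraries, 100 regroupings that exchange libraries only within a number were also fitted with the replicate block. Of these 1, the real one with 7569 genes, gave as many, and the highest other gave 5174. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave the largest count, of 4310, 4095 and 5783 genes for CSF, meninges and parenchyma against blood, 289 and 3759 for meninges and parenchyma against CSF and 1375 for parenchyma against meninges. The highest other split gave 0 genes by edgeR in each case. Each other split mixed both compartments in each of its groups, which put their differences into the spread. Few calls were thus built in, and neither these 0 calls nor the unadjusted counts below give a chance level. At an unadjusted p under 0.05 the highest other splits gave 670, 588, 620, 1174, 1211 and 1335 genes, against 5366, 5135, 6443, 1824, 4926 and 2998 in the real splits. In the 5 comparisons with numbers read as pairing the libraries, 4 of the 10 splits, the real one included, part all 3 pairs. The other 6 keep a pair together. Of neither kind did a split besides the real one give a call by edgeR, but all these mixed compartments, so this gives no chance level.

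Libraries with the same number deviated together from their compartment means, with a median correlation of 0.278. Unequal depth is argued against, since after thinning to a common total the median was 0.259. With each gene's linear trend on the share of reads aligned to several places removed, the median was 0.267. This argues against that share as a cause acting in proportion. By rank, the prediction that the library numbered 2 would hold the same extreme rank in all 4 compartments was not met. It did so in at most 2. A wider rule over all numbers, not the one predicted, leaves the share open, as the library numbered 1 was lowest in 3. A shared preparation day, a shared animal or pool, or stage of disease remain open, as the labels give none of them. No biological explanation was tested.

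In CSF 434 genes were higher than in both blood and parenchyma and 388 lower than in both, 822 in all. Independent lists would share 313 and 394, so that the count of lower genes did not exceed that value, simulated unchanged libraries, with almost no calls, shared 0 on average, and part of any excess may come from the CSF libraries that both comparisons use. The count was 715 after thinning to a common depth, and with the replicate block 1392, 755 higher and 637 lower, and 1211 after thinning, which argues against depth as the whole cause, while the block does not test a batch carried by the numbers, since each number occurs once in every compartment. Without CSF replicate 2 it was 552, or 67.2% of 822, and 687 or 714 without replicate 1 or 3; the bound set beforehand, 2 in 3, was just met, but a margin of 5% around it, added after the value was seen, leaves open how much rests on that library, and the lower genes numbered 258 without it and 256 without blood replicate 1. Meninges did not enter these counts. The 434 genes had a median log2 difference to blood of 0.505 in CSF and 0.250 in meninges, and the 388 genes -0.467 and -0.235. The 2 sets are therefore not shown to be particular to the fluid. A state of T cells behind them was not tested apart from the sampling of the fluid.

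Of the genes called between meninges and CSF 78.5% were higher in meninges, a share that was 57.7% with the replicate block, while 166 of 174 genes past 2-fold were higher with it. A floor on low genes is argued against as the whole cause of the calls without the block and of changes past 2-fold: of called genes with at least 10 CPM in CSF 70.8% of 195 were higher without the block, and past 2-fold 32 of 32 without it and 35 of 35 (100%) with it. For smaller changes called with the block a floor stays open, as 46.9% of 786 called genes with at least 10 CPM were higher with it, against 90.4% of 260 below. RNA or cells of other types in amounts that differ between libraries may contribute, although the sort for fluorescent cells is meant to remove such cells: the 216 genes higher in both meninges and parenchyma than in CSF deviated together within compartments, with a mean pairwise correlation of 0.162, at percentile 100 of 1000 random lists matched on mean expression (median -0.000980), which genes regulated together in T cells would also show. The random lists were not matched on being called, so other called genes might reach this percentile too. The median deviation of the 216 genes from the compartment mean was small, from -0.0855 to 0.0836 log2 units over the meninges and parenchyma libraries. With 1 other source at a fixed ratio between the sites as the whole cause, the 227 genes higher in meninges than in CSF would share 1 ratio of excess over CSF. They deviated from it with a mean square of 3.51 squared standard errors, against 0.975 on average in simulations with 1 ratio. The simulations redrew the same genes without choosing them anew for a high meninges value, and part of the gap may come from that choice. How strongly the gap counts against 1 such source stays open. Markers of other cells could not be examined without gene names.

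Meninges replicate 3 held 980 genes with counts in no other library, at most 6 counts each, where the other libraries held 45 to 213. After thinning it still had 17371 genes with counts, against 14072 to 15656 in the others.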
